A study of Mus musculus with 4 samples.

How the data were processed

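RNA from mouse aortic endothelial cells (MAECs, a purchased cell line, per the labels' protocols) was sequenced after 48 h with exosomes, small vesicles that cells release, from brown adipose tissue. The exosomes came from diabetic db/db mice, which carry a mutated leptin receptor on both alleles, or from non-diabetic db/m mice, which carry it on 1 allele. There were 2 libraries in each of the 2 groups, named here db/db replicate 1 and 2 and db/m replicate 1 and 2. Total RNA was isolated with Trizol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. Nothing in the labels says whether the replicates were separate cultures, so the p-values of single genes measure the spread between these libraries, which may be technical. The camera p-values of gene lists at a preset correlation rest on the spread across genes, and the exact binomial p-values on counts of lists.

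The authors deposited 1 table with a raw count per gene and library, in columns named as counts per the file headers. HISAT2 and HTSeq 0.11.2 are named, with no role or order, per the submitters' processing notes. Those notes name the human build GRCh38, whereas all 44612 gene identifiers in the deposited table are mouse Ensembl identifiers, so the build behind the counts is open and no coordinates are given. How reads with several matching positions were counted, and whether strand was used, is not given in the sources used here. The authors also deposited FPKM (fragments per kilobase of gene and per 1e6 counts) values, and division of each count by the FPKM and the column total gave a whole-number gene length for every gene, within a tolerance of 0.001. The deposited log2 columns hold the log2 of 1 + FPKM, as checked against the FPKM columns. No value column of another sample was present, and 0 of the 44612 entries lacked a gene. Each listed gene had at least 1 count over the 4 libraries. Symbols came from the deposited table, with 44582 different symbols, and 44391 of the identifiers were matched to the GENCODE M21 annotation, which was used for gene type, GC content, CpG density and transcript sequence. The table held 0 of the 37 mitochondrial genes of that annotation, and the list of mitochondrially encoded genes was not analysed here.

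Library totals ran from 1308284 to 1726912 counts. A count of 0 allowed up to 3 counts, which was 1.74 CPM (counts per 1e6 counts) of the unscaled total in db/db replicate 1 and 2.29 CPM in db/m replicate 2. These floors do not apply to the TMM-scaled levels given below. In db/db replicate 1 a single count was 3.27 TMM-scaled CPM, since its TMM factor was 0.179. Shares of counts carry 95% exact binomial intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

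Differences between the groups were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, two-sided, current form) in R 4.3.3 on the deposited counts, with TMM scaling and the filterByExpr filter at its minimum count of 10, which left 19824 genes. Fold changes are db/db minus db/m on the log2 scale. The SE beside them is the absolute log2 fold change over the square root of the F statistic. It is not an error given by the fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels per group are TMM-scaled CPM, as mean ± SD over 2 libraries. The TMM factors were 0.179 and 1.06 in db/db replicates 1 and 2 and 2.28 and 2.32 in db/m replicates 1 and 2. The test was tried on simulated counts drawn from the real means and library sizes, with 200 changed genes among 19824. At the estimated biological coefficient of variation of 0.423, edgeR recovered 7 of 100 genes changed 4-fold and 81 of 100 changed 16-fold, with 2 false calls. At a coefficient of 0.1 it recovered 66 and 98 of 100. The simulated genes all had the same dispersion, with no GC trend and no library of unlike profile. Recovery and false calls in the real data may therefore differ.

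There were 31 gene lists, for calcium handling, endothelial function, stress, signalling, metabolism, cell identity, other cell types and RNA quality. The lists, the groups, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the 29 lists with enough tested members, and again with an estimated correlation and with fry. Named genes were, as no gene was called, the 5 with the smallest p in each direction (predicted genes with no gene name were skipped). To these were added Nos3, Edn1, Icam1, Vcam1, Pecam1, Cdh5 and Ucp1, up to 4 members with the smallest p from each called list, and the 2 with the smallest p from each of the calcium lists. Genes named outside this rule were chosen after their values were seen, apart from Lepr, which was planned as donor background. They include the genes called over their list alone (Plk1, Bag3, Hspb1, Hspa1a and Aif1) and the donor markers Adipoq, Lep and Plin5.

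A family of near-identical genes was defined after the counts were seen, as the 12 listed genes whose transcript aligned to that of Gm10800 over at least 500 bp at 70% identity or more (blastn 2.17.0). That this sequence resembles the major satellite repeat is background knowledge, and was not tested on reads. For comparison with other genes, the count density of a list (counts per kilobase over its members, relative to the counts outside that family) was set against 10000 random lists of protein-coding genes matched on GC content and length.

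Alternatives planned at the start were RLE and total-count scaling, no filter or a CPM minimum of 1, DESeq2 1.42.0, limma-voom, the legacy form of the edgeR test, limma-trend on the FPKM values with pseudocounts of 0.1 and 1, the replicate number as a block, other thresholds and each library left out in turn. Added after the data were seen were the satellite family left out, replicate numbers crossed, GC content, GC content with length, or CpG density smoothed out per library with loess offsets (span 0.4), upper-quartile scaling with the legacy form, and random lists matched on CpG density as well for the 29 lists with at least 8 protein-coding members. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the other steps.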

Results

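The 4 libraries of endothelial cells, 2 after exosomes from diabetic db/db mice and 2 after exosomes from non-diabetic db/m mice, held 1726912 and 1451047 counts in db/db replicates 1 and 2 and 1663311 and 1308284 in db/m replicates 1 and 2. Genes with at least 10 counts numbered 2369 and 16473 in the db/db libraries and 21184 and 20192 in the db/m libraries. The median count of a listed gene was 1 and 6 in the db/db libraries and 8 and 7 in the db/m libraries.

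The comparison between db/db and db/m exosomes asks how brown adipose exosomes of diabetic and of healthy mice differ in their effect on endothelial gene expression. The most abundant gene in every library was Gm10800 (ENSMUSG00000075014). It belongs to a family of 12 related genes, among them Gm21738, Gm10722, Gm11168 and Gm10801, which GENCODE M21 lists as protein-coding and whose sequence resembles the major satellite repeat of mouse centromeres. The family took 93.8% of the counts in db/db replicate 1 (95% exact binomial interval 93.8 to 93.8), 63.5% in db/db replicate 2 (63.4 to 63.6), 17.98% in db/m replicate 1 (17.92 to 18.04) and 23.6% in db/m replicate 2 (23.5 to 23.7). The group means were 78.7% ± 21.4 and 20.8% ± 3.96 (SD, n = 2), a difference of 57.9 percentage points, and with 2 libraries against 2 the two-sided exact permutation test gave p = 0.333, the smallest it can give. The fold changes of the 12 genes lay between 4.90 and 5.82 with TMM scaling, with edgeR adjusted p between 0.353 and 0.436, and between 1.82 and 2.79 with total-count scaling. The aligned parts of the members were 89.8% to 93.4% identical to Gm10800, so how the reads were divided among them is uncertain. Counts outside the family were 107091 and 529340 in the db/db libraries and 1364201 and 999744 in the db/m libraries.

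**Figure D1:**
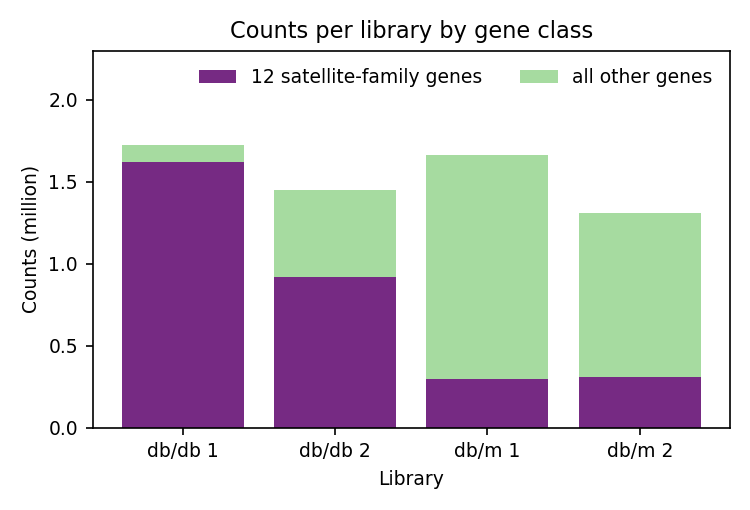
Counts (y axis) in each of the 4 libraries (x axis), split into the 12 satellite-family genes and all other genes. The family held 93.8% and 63.5% of the counts in the db/db libraries and 17.98% and 23.6% in the db/m libraries.

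Among named genes outside the family, those with the smallest p were Neat1, Ext1, Zbp1, BC026513 and Kcnmb1 on the higher side in db/db and Mcrs1, Nckap5l, Galr2, C1ql2 and Elfn2 on the lower side. Neat1, the long noncoding RNA that scaffolds nuclear paraspeckles, had 54.8 ± 8.09 CPM in db/db and 12.03 ± 0.829 in db/m (SD, n = 2), a log2 fold change of 2.19 (SE 0.431; edgeR adjusted p = 0.353). Zbp1, a sensor of Z-form nucleic acids, had 23.0 ± 4.81 and 3.04 ± 0.831 CPM, and Kcnmb1, a subunit of the calcium-activated potassium channel, 25.8 ± 9.86 and 3.25 ± 0.138 CPM. In counts, Neat1 had 15 and 87 in the db/db libraries and 41 and 36 in the db/m libraries. Zbp1 had 6 and 38 against 13 and 7, and Kcnmb1 10 and 27 against 12 and 9. Their higher levels in db/db replicate 1 thus depended on its TMM factor of 0.179. Mcrs1 had 2.68 ± 0.839 CPM in db/db and 37.3 ± 13.1 in db/m, a log2 fold change of -3.86 (SE 0.587), and Nckap5l had 7.10 ± 0.783 and 84.4 ± 32.6 CPM, a log2 fold change of -3.54 (SE 0.490). The db/db level of Mcrs1 rested on 1 and 3 counts. Galr2, a receptor for the neuropeptide galanin, had a log2 fold change of -3.58. In the edgeR test none of these genes was called. Nckap5l and Elfn2 were called by DESeq2, limma-voom and the legacy form of the edgeR test. Mcrs1, Galr2 and BC026513 were called by limma-voom and the legacy form, C1ql2 by the legacy form, and Neat1, Ext1 and Zbp1 by limma-voom. The edgeR test called 0 of 19824 genes, with a smallest adjusted p of 0.353, while 2592 genes had an unadjusted p under 0.05, of which 880 were higher and 1712 lower in db/db. The median gene lay at -0.11 on the log2 scale, and at -1.98 with total-count scaling, under which 5 genes were higher and 3629 lower at that unadjusted threshold. With GC content smoothed out 1126 were higher and 965 lower, with GC content and length 1198 and 914, and with CpG density 920 and 933. DESeq2 called 249 genes (12 higher, 237 lower), limma-voom 211 (73 higher, 138 lower) and the legacy form of the edgeR test 123 (34 higher, 89 lower). These 3 tools shared 28 genes. The edgeR test also called genes without db/db replicate 1 and without db/db replicate 2, in both cases more of them higher than lower. Each of these fits leaves 1 library in the db/db group.

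Genes shared by those 3 tools were Dyrk1b, Map3k11, Ercc2, Capn15, Celsr2, Nckap5l, Elfn2 and 18 others on the lower side, with a GC content between 55.4% and 64.9%, and the satellite-family genes Gm10720, Gm10715 and Gm17535 on the higher side. Apart from Nckap5l and Elfn2 they were looked up after their values were seen. Fold changes followed GC content across genes (Spearman correlation -0.54 over 19789 genes, which are not independent replicates). In the quintile of tested genes with the lowest GC content the median log2 fold change was 0.67, with 418 genes higher and 61 lower at an unadjusted edgeR p under 0.05. In the quintile with the highest GC content it was -1.17, with 8 higher and 1003 lower. Within each library, genes of the top GC quintile had 1.44 and 2.70 times the count density of the bottom quintile in db/db replicates 1 and 2, and 11.3 and 4.72 times in db/m replicates 1 and 2.

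**Figure D2:**
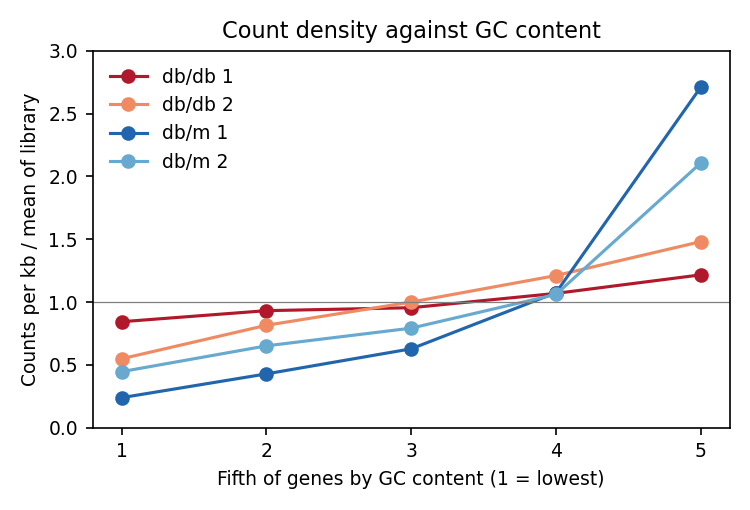
Count density outside the satellite family, as counts per kilobase relative to the mean of the library (y axis), for genes in 5 classes of GC content from lowest to highest (x axis), with 1 line per library. The top class over the bottom class gave 1.44 and 2.70 in the db/db libraries and 11.3 and 4.72 in the db/m libraries.

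Genes of endothelial function were measured at low counts. Nos3, which makes nitric oxide in endothelium, had 4 and 18 counts in the db/db libraries and 163 and 54 in the db/m libraries, 12.8 ± 0.402 against 32.2 ± 18.8 CPM, a log2 fold change of -1.33 (SE 0.575; edgeR adjusted p = 0.393). Edn1, the precursor of the vasoconstrictor endothelin, had 0 and 4 counts in db/db and 15 and 17 in db/m. The adhesion genes Icam1 and Vcam1 had log2 fold changes of -0.54 (SE 0.631) and 1.30 (SE 0.711), and the junction genes Pecam1 and Cdh5 of 1.99 (SE 0.729) and -0.28 (SE 0.587), with edgeR adjusted p between 0.371 and 0.837. Of the 31 genes of the endothelial identity list, 8 were higher and 23 lower, none called by edgeR over all genes or adjusted over the list alone, with a median log2 fold change of -0.365 (camera adjusted p = 0.59). Sox18, an endothelial transcription factor with 1 and 0 counts in db/db and 93 and 94 in db/m, had a log2 fold change of -4.93 (SE 2.00; edgeR adjusted p = 0.379), and was looked up, as was Sox17, after its values were seen. It was called by limma-voom, the legacy form, limma-trend on FPKM and, in the edgeR test, without db/db replicate 1. Of this list DESeq2 called 0 genes, limma-voom 2 (Sox17 and Sox18) and the legacy form 1, and the edgeR test without db/db replicate 1 called 3 (Pecam1 higher, Sox17 and Sox18 lower). Camera put this list lower in db/db without a filter on low counts (adjusted p = 0.00109) and with the CPM filter (adjusted p = 0.012), in a range of 0.00109 to 0.99 over the alternatives. In those 2 settings 9 of 10 and 6 of 7 called lists were lower, so the endothelial list did not stand apart. Set against random lists of the same GC content and length, the count density of that list lay at percentile 12.8 and 79.1 in the db/db libraries and 53.02 and 15.3 in the db/m libraries.

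Calcium handling, the subject in the title of the series, showed no gene called by the edgeR test in the planned setting. DESeq2 called 5 genes (Cacna1h, Piezo1, Itpr3, Nfatc1 and Plcd1, the last named for these calls), limma-voom 1 (Itpr3) and the legacy form 0, and limma-trend on FPKM 3 and 6 at pseudocounts of 0.1 and 1, all lower in db/db. Calls over all genes were mostly lower in these settings too. They were 237 of 249 with DESeq2, 138 of 211 with limma-voom, and 1467 of 1479 and 2661 of 2670 on FPKM. The median gene on FPKM lay at -2.47 and -1.68. Of 31 tested genes of calcium entry, 14 were higher and 17 lower in db/db, with a median log2 fold change of -0.29, and Cacna1h, a voltage-gated calcium channel, and Piezo1, a mechanosensitive channel, were at -1.63 (SE 0.405) and -1.75 (SE 0.518). Among 29 genes of calcium stores and pumps, 17 were higher and 12 lower with a median of 0.32. Itpr3, an inositol trisphosphate receptor, was at -2.15 (SE 0.682) and Atp2b1, a plasma membrane calcium pump, at 1.57 (SE 0.530). Among 34 calcium signalling genes, 17 were higher and 17 lower with a median of -0.08, with Nfatc1 at -1.92 (SE 0.491) and Gnaq at 1.78 (SE 0.552). The edgeR adjusted p of these 6 genes lay between 0.353 and 0.359, and 0 were called by edgeR adjusted over the list alone. GC content was 53.7% to 60.0% in the lower genes Cacna1h, Piezo1, Itpr3, Nfatc1 and Plcd1. It was 42.6% in Atp2b1 and 46.9% in Gnaq, both higher. The camera adjusted p was 0.659, 0.485 and 0.978 for entry, stores and signalling. Without a filter on low counts, camera put calcium entry (adjusted p = 0.00109) and calcium signalling (adjusted p = 0.0131) lower in db/db, and with the CPM filter calcium entry (adjusted p = 0.012). Camera compares a list with the other tested genes, and 44612 and 35288 genes were tested in these settings rather than 19824. Of the lists called there, 9 of 10 and 6 of 7 were lower, so this was not particular to calcium genes. With CpG density smoothed out calcium stores were higher (adjusted p = 0.0476). Over all alternatives the adjusted p ranged from 0.00109 to 0.988 for entry, 0.0476 to 0.988 for stores and 0.0131 to 0.991 for signalling.

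Of the 29 lists tested with camera, 4 were called, with 0 members called by edgeR over all genes and 0 adjusted over the list alone. Of their members DESeq2 called 1 (Srebf1), limma-voom 2 (Rpl7 and Zbp1), and the legacy form 4 (Rpl4, Rpl7, Cd36 and Fabp4, where Rpl4, Cd36 and Fabp4 were looked up after the calls were seen), and the edgeR test called 3 without db/db replicate 1 and 14 without db/db replicate 2. All 4 lists had a camera adjusted p = 0.988 with an estimated correlation. So did most of the 29 lists, with the highest at 0.991, and fry gave adjusted p of 0.719 to 0.987. With 2 libraries per group these 2 settings did not tell the lists apart. Ribosomal protein genes, 36 of 39 higher in db/db, had a median log2 fold change of 1.34 (camera adjusted p = 8.47e-07), with Rpl7 at 3.10 (SE 1.01), Rps3 at 2.37, Rps9 at 2.70 and Rpl10 at 2.97. Their count density lay at percentile 100 of matched random lists in db/db replicate 1, 18.04 in db/db replicate 2, 10.4 in db/m replicate 1 and 99.96 in db/m replicate 2, and with CpG density matched as well at 100, 15.7, 0.17 and 94.7. Without db/db replicate 1 the median relative to the median gene went from 1.45 to -0.705 (adjusted p = 0.209, in a range of 3.26e-33 to 0.988 over the alternatives), and without db/db replicate 2 to 2.52. With total-count scaling 2 of the 39 ribosomal, 5 of the 29 fatty acid and 5 of the 28 interferon genes were higher, with the list medians still above the median gene. Fatty acid and PPAR genes, 20 of 29 higher with a median of 0.88 (adjusted p = 0.0195), included Ppargc1a, a coactivator of mitochondrial biogenesis, at 2.20 (SE 0.618), Acadm, which oxidises medium-chain fatty acids, at 2.65 (SE 0.805), and, on the other side, Srebf1 at -2.13 (SE 0.544) and Ppara at -1.68 (SE 0.515). The adjusted p of that list was 0.674 without db/db replicate 1 (median relative to the median gene 0.494, from 0.986), 0.0771 without db/m replicate 1, 0.197 without db/m replicate 2, 0.297 with the satellite family left out and 0.0655 with GC content smoothed out, 0.468 with no filter and 0.291 with the CPM filter, in a range of 0.000118 to 0.988 over its alternatives, with medians from 0.462 to 1.18.

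Interferon response genes, 20 of 28 higher in db/db, had a median of 0.58 (camera adjusted p = 0.00922, and adjusted p = 0.988 with an estimated correlation), with Zbp1 at 2.91 (SE 0.602), Ddx58, the RNA sensor RIG-I, at 1.83 (SE 0.631), Usp18 at 2.37 (SE 0.872) and Xaf1 at 2.04 (SE 0.837). Relative to the median gene the median was 0.683. It was 0.523 without db/db replicate 2 (adjusted p = 0.154), 0.314 with no filter (adjusted p = 0.1) and 0.4 with the CPM filter (adjusted p = 0.0505), and 1.03 without db/db replicate 1 and 1.10 without db/m replicate 1. The adjusted p ranged from 0.00181 to 0.988 over the alternatives. Their count density lay at percentile 42.4 and 66.8 of matched random lists in the db/db libraries and 0.03 and 0.07 in the db/m libraries. Leukocyte markers, which were not called (adjusted p = 0.247), lay at 17.7 and 91.6 against 0.29 and 0.54, and camera called them without db/db replicate 1. Immediate early genes, 24 of 25 lower in db/db, had a median of -1.04 (adjusted p = 0.00291, and adjusted p = 0.988 with an estimated correlation), with Fosl1 at -2.50 (SE 0.529), Klf2, a flow-responsive endothelial factor, at -1.63 (SE 0.501), and the feedback inhibitors Spry4 and Dusp4 at -1.95 and -1.88. The median GC content of the list was 54.4%, and with GC content smoothed out the median relative to the median gene went from -0.934 to -0.189 (adjusted p = 0.118), and with CpG density smoothed out to -0.103 (adjusted p = 0.645). Without db/db replicate 2 it was -0.459 (adjusted p = 0.293), in a range of 2.92e-08 to 0.988 over the alternatives, with medians from -1.53 to -0.103.

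**Figure D3:**
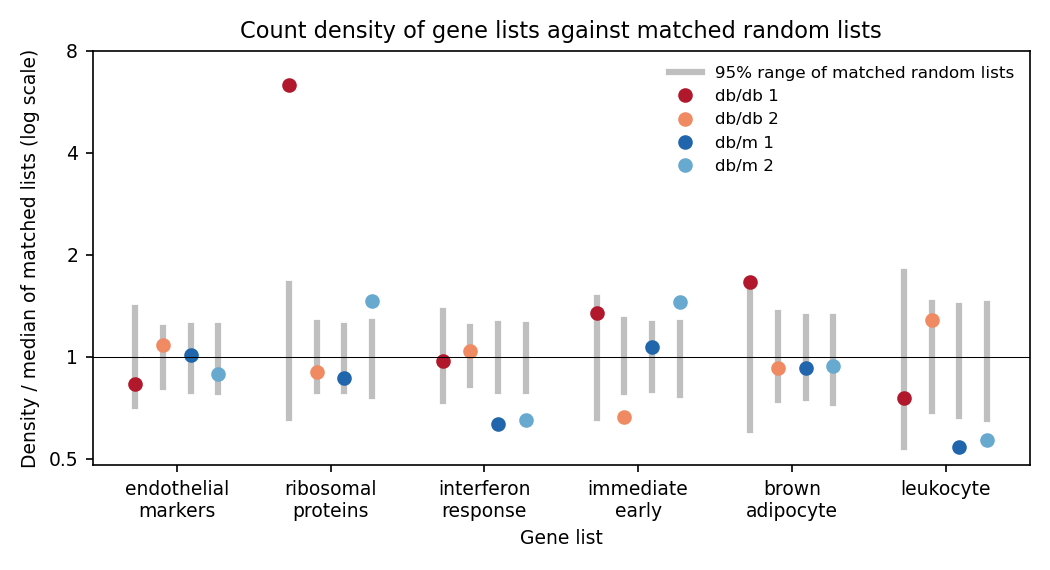
Count density of 6 gene lists in each library, divided by the median of 10000 random lists matched on GC content and length (y axis, log scale), with 1 point per library and grey bars for the 95% range of the random lists. Ribosomal proteins in db/db replicate 1 stood 6.35 times above the median of their random lists, and the endothelial markers lay inside the range in all 4 libraries.

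The other lists were not called, with camera adjusted p between 0.247 and 0.978 in the planned setting, but some were called under alternatives. Lower in db/db were nitric oxide and vasodilation (adjusted p = 0.00109 with no filter, 0.012 with the CPM filter), angiogenesis and Notch (0.00117 and 0.0131), and epithelial markers (0.00506 and 0.0234). With no filter alone, TGF-beta (0.00819) and glycolysis (0.0342) were lower. Counting all lists, 9 of the 10 called with no filter and 6 of the 7 called with the CPM filter were lower. Higher were leukocyte markers without db/db replicate 1 (0.0102), and oxidative stress without db/db replicate 2 (0.0308). So were fibroblast and matrix genes without db/db replicate 2 (0.0308) and with GC content smoothed out (0.0111), and smooth muscle with GC content smoothed out (0.04). Over the alternatives the adjusted p of these lists ranged up to 0.988, or 0.99 for angiogenesis, epithelial and TGF-beta genes. Median log2 fold changes were -0.57 for nitric oxide and vasodilation (28 tested), -0.106 for vasoconstriction (16), 0.08 for inflammatory adhesion (20), 0.33 for oxidative stress (27), 0.04 for the unfolded protein response (29) and -0.35 for p53 targets (23). They were 0.07 for the cell cycle (38), 0.27 for nuclear-encoded oxidative phosphorylation (28), -0.11 for glycolysis and hypoxia (30), 0.15 for cholesterol synthesis (24), -0.39 for TGF-beta and mesenchymal transition (26) and -0.37 for angiogenesis and Notch (32). Heat shock genes had 0.31 (15), barrier and junction genes 0.12 (23), coagulation and fibrinolysis 0.22 (19) and lysosome and autophagy 0.19 (27). Markers of other cell types had 0.40 for smooth muscle (12), -0.05 for fibroblasts and matrix (20), 0.34 for leukocytes (8), -0.97 for epithelium (12) and -0.251 for erythroid cells (2, too few for camera). Median, mean and test differed in sign for vasoconstriction, inflammatory adhesion, the unfolded protein response, oxidative phosphorylation, cholesterol synthesis, fibroblasts, heat shock and barrier genes. No list had a member called over all genes in the edgeR test. Over all lists DESeq2 called 10 genes, limma-voom 6, the legacy form 8 and limma-trend on FPKM 24 and 68, and the edgeR test called 13 without db/db replicate 1 and 19 without db/db replicate 2. Adjusted over the list alone, the calls were Plk1, a mitotic kinase, at -2.60 (SE 0.456), the chaperone genes Bag3 at -2.72 (SE 0.528), Hspb1, with 0 and 1 counts in db/db and 35 and 44 in db/m, and Hspa1a, with 1 and 2 against 68 and 33, and Aif1, a marker of macrophages, at 2.61 (SE 0.608). These 5 genes had an edgeR adjusted p = 0.353 over all genes.

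Transcripts of the exosome donor tissue were looked for with 22 brown adipocyte markers, of which 17 were tested, 10 higher and 7 lower in db/db, with 0 called and a median log2 fold change of 0.50 (camera adjusted p = 0.672). Ucp1, the uncoupling protein of brown fat, had 11 and 1 counts in the db/db libraries and 16 and 13 in the db/m libraries, a log2 fold change of 1.91 (SE 1.51; edgeR adjusted p = 0.582). Its direction rested on db/db replicate 1, without which the value relative to the median gene was -2.61. Adipoq had 6, 8, 6 and 2 counts in the same order of libraries, Lep 4, 13, 19 and 18, and Lepr, the receptor mutated in db/db mice, 9, 14, 46 and 42, the last looked up as donor background. Plin5, a lipid droplet protein with 0 and 14 counts in db/db and 114 and 61 in db/m, had a log2 fold change of -2.20 (SE 1.35; edgeR adjusted p = 0.487). It was the 1 marker called with limma-trend on FPKM (log2 fold change -5.31 with a pseudocount of 0.1, adjusted p = 0.0284). In that setting the median gene lay at -2.47 and 1467 of 1479 calls were lower.

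Libraries of 1 group were not always closest to each other. Across 19824 genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.772 between the db/m libraries and 0.477 between the db/db libraries, while db/db replicate 1 had 0.508 with db/m replicate 2. The first principal component held 61.7% of the variance, with db/db replicate 1 at -165 and the other libraries at 14.9, 97.3 and 53.2. The libraries stood in the same order by counts outside the satellite family and by the density ratio of the top to the bottom GC quintile. Closeness of libraries therefore cannot be told apart from depth or the GC trend. No pair of libraries held identical values.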

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

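The settings with GC content, GC content and length, or CpG density smoothed out, the satellite family left out, crossed numbers, upper-quartile scaling, and all settings for the satellite share, library similarity and matched lists were chosen after the data were seen. Genes called numbered 0 with edgeR under RLE and total-count scaling, under no filter and the CPM filter, with the satellite family left out and with any of the smoothed trends. They numbered 249 with DESeq2, 211 with limma-voom, 123 with the legacy form, 86 with upper-quartile scaling in the legacy form, 1479 and 2670 with limma-trend on FPKM at pseudocounts of 0.1 and 1, 2590 at an unadjusted p under 0.05 with a log2 fold change of at least 1, and 0 to 494 with 1 library left out, where the lone library of a group is assumed to vary like the other group. Upper-quartile scaling in the current edgeR form could not be fitted. The cause of these differences was not tested. Lists called went from 4 to 0 with an estimated correlation, 0 with fry, 10 with no filter, 7 with the CPM filter and 2 with GC content and length smoothed out. With an estimated correlation and with fry no list had an adjusted p below 0.719, so these 2 counts say little about single lists. Brown adipocyte markers called numbered 1 and 1 (Plin5) on FPKM. The group difference in satellite share was 20.1 points with Gm10800 left out, by construction, and 42.7 to 73.0 with 1 library left out.

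With the replicate number as a block 0 genes and 4 lists were called, and 945 genes had an unadjusted p under 0.05; among the called and calcium lists and the named genes, the block turned calcium signalling alone. Differences between replicates 1 and 2 correlated at -0.297 between the groups. With 4 libraries, and db/db replicate 1 far from the others, that value cannot tell whether equal numbers share more than a number. With the numbers crossed as a block 0 genes and 4 lists were called.

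Values relative to the median gene turned direction as follows, and the cause was not tested. With GC content smoothed out calcium entry was at 0.236 and Icam1 at 0.238. With GC content and length smoothed out calcium entry was at 0.0821 and Icam1 at 0.155. With CpG density smoothed out calcium entry was at 0.322 and Cdh5 at 0.0512. For calcium signalling, at 0.0279, the direction of the camera test turned with GC content (median 0.00578) and CpG density (0.41) smoothed out and with the replicate block (-0.0295, adjusted p = 0.926). The median itself turned with the replicate block, no filter (-0.421), the CPM filter (-0.322), GC content and length smoothed out (-0.0663) and crossed numbers (-0.0515), and ranged from -0.199 to 0.0473 with 1 library left out. Calcium stores were at -0.142 with no filter and -0.0542 with the CPM filter. With limma-voom Cdh5 was at 0.00324 and Ucp1 at -0.407. With 1 library left out ribosomal proteins ranged from -0.705 to 2.52, Icam1 from -1 to 0.122, Cdh5 from -0.675 to 0.227 and Ucp1 from -2.61 to 3.37. Over the 38 named genes, 8 of 728 values turned and 60 passed the threshold in the same direction. Depth outside the satellite family, 107091 counts in db/db replicate 1, limits the values of single genes there.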

Other observations

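The tests here on the source of the counts, on library size, on the GC content of the family, on the kind of exosome, on the GC trend, on db/db replicate 1 and with random lists matched on CpG density were chosen after the result, or unmatched values close to it, had been seen, and so was the choice of genes and classes described. The test with CpG density smoothed out was written down before its result was seen.

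Genes of sensory receptors, which are seldom transcribed outside their own tissues, carried counts in all 4 libraries. Of 1087 olfactory receptor genes, 62.5% and 93.2% had a count in db/db replicates 1 and 2 and 80.2% and 87.6% in db/m replicates 1 and 2, and their density was 0.617, 0.476, 0.122 and 0.233 times that of all genes outside the satellite family. Of 296 vomeronasal receptor genes, 74.0%, 91.9%, 87.2% and 89.2% had a count. Ttn, the giant muscle gene, had 56, 314, 338 and 339 counts in the same order, and Actb, the cytoskeletal actin of nearly all cells, had 60, 5, 21 and 75. Lars2 had 2280, 58, 319 and 3204 counts, Eef1a1, a translation factor, 166, 8, 12 and 130, and Scd1, a fatty acid desaturase, 187, 18, 6 and 40. In db/db replicate 1, 9 of 29 lists lay outside the 95% range of matched random lists, and 7 with CpG density matched as well. Fatty acid genes lay there at percentile 99.4, heat shock genes at 99.55 and fibroblast and matrix genes at 99.42, and with CpG density matched at 99.57, 99.58 and 99.63. Oxidative stress genes were at 99.46, and at 99.03 with CpG density matched. The 1 list below the range was inflammatory adhesion, at percentile 0, and at 0.01 with CpG density matched. Oxidative phosphorylation went from 98.38 to 90.19 and TGF-beta genes from 98.85 to 96.18, both back inside the range. Brown adipocyte markers lay at 98.3, and matching them on CpG density as well left as few as 2 genes to draw from for at least 1 member, so that value is not used, although it is 1 of the 7. Leukocyte markers lay at percentile 17.7 and 91.6 in the db/db libraries and 0.29 and 0.54 in the db/m libraries, and with CpG density matched as well at 44.9, 91.41, 1.79 and 8.89. Without that matching interferon genes lay at 42.4 and 66.8 against 0.03 and 0.07.

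Counts outside the satellite family lay on nearly all gene classes. All 4 libraries had been given exosomes, so an effect of exosomes on this was not tested. Endothelial mRNA as their main source is argued against by the endothelial list, which was above the 95% range of matched random lists in 0 of the 4 libraries. Genomic DNA as their whole source in db/db replicate 1 is argued against by the ribosomal protein list, at percentile 100 with or without CpG density matched. In db/m replicate 2 genomic DNA cannot be told apart from a mixture with RNA, since that list was at percentile 99.96, but at 94.7 with CpG density matched. Nor can it in db/db replicate 2 and db/m replicate 1, where neither list was above the range but 8 lists lay outside it, 5 of 29 (one-sided exact binomial p = 0.0136) and 3 of 29 (p = 0.175, same exact test), with 1.45 each by chance and the lists taken as independent. With CpG density matched as well 3 and 3 lay outside it (exact binomial p = 0.175 each), so the excess in db/db replicate 2 depended on the matching. The lists outside it were then immediate early genes at percentile 0.04, p53 targets at 1.74 and smooth muscle at 98.78 in db/db replicate 2, and interferon at 0.07, ribosomal protein at 0.17 and leukocyte genes at 1.79 in db/m replicate 1. The matching leaves out how uniquely reads map.

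The satellite family held a higher share of the counts in both db/db libraries. Library size, taken as the total count, is argued against, since 1 of the db/db libraries had a total inside the range of the db/m libraries. That total includes the counts of the family itself. It does not measure the depth of the other genes, which was lower in both db/db libraries. The low GC content of the family as the whole cause is argued against too, since the 74 other tested genes at its GC content had a median log2 fold change of 0.99 and, at the upper end of their 95% range, 2.65, below the lowest of the family at 4.90. The kind of exosome cannot be told apart from differences in library preparation that fall along the groups, and 2 libraries against 2 give no exact permutation p below 0.333. The biological explanation, a response to the exosomes, stays open and untested.

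Of the lists shifted between the groups, the immediate early list may follow the GC trend between the libraries, since its adjusted p was 0.118 with GC content smoothed out and its median relative to the median gene went from -0.934 to -0.189. Against lists matched on GC content and length it stood at percentile 92.8 and 0.07 in the db/db libraries and 71.4 and 99.81 in the db/m libraries, and with CpG density matched as well at 52.24, 0.04, 9.18 and 68.19, so that db/db replicate 2 alone stayed outside the 95% range. Why it did is open. The ribosomal protein shift may come from db/db replicate 1, without which it was -0.705. For the interferon list, the tables argue against the GC trend alone, since its median did not fall with GC content smoothed out (0.683 to 0.762, camera adjusted p = 0.00538). The CpG trend alone was argued against by the rule written before its result (camera adjusted p = 0.0257). The median did fall to 0.511, so a part of the shift may follow CpG density. Both p-values rest on the preset correlation of 0.01, while 0.159 was estimated for this list. With CpG density matched as well the list lay at percentile 69.35 and 71.22 in the db/db libraries and 0.07 and 0.11 in the db/m libraries. Without db/db replicate 2 the median of the interferon list fell to 0.523. Its camera call was lost with no filter (adjusted p = 0.1, median 0.314) and with the CPM filter (adjusted p = 0.0505, median 0.4). At an equal median, the adjusted p was 0.988 with an estimated correlation and 0.719 with fry. No list was called in those 2 settings, so they say little about this list in particular. The adjusted p ranged from 0.00181 to 0.988 over its alternatives. An effect of the kind of exosome on interferon genes stays an untested hypothesis. Leukocyte markers stood low in the same db/m libraries, at 0.29 and 0.54, or 1.79 and 8.89 with CpG density matched, and whether these shifts share an origin was not tested.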
